A study of Homo sapiens with 16 samples.

How the data were processed

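RNA of 4 human cell lines of the B cell lineage was measured on Affymetrix expression arrays. RPMI8226, KMS-11 and U266 derive from multiple myeloma, a cancer of plasma cells; IM-9, which the labels also list as a myeloma line, is widely described as an Epstein-Barr virus transformed B lymphoblastoid line. Each line was given as parental cells kept at 20% oxygen and as hypoxia-resistant (HR) cells kept at 1% oxygen, both for 24 hours, with 2 arrays per line and condition. That makes 8 groups and 16 arrays, grouped by their labels. HR cells were measured only at 1% oxygen and parental cells only at 20%, so resistance and the oxygen level at harvest are confounded in every comparison.

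The deposited table holds log2 intensities of 33297 probe sets, already summarised over probes. Affymetrix Expression Console 1.3.0 is named in the submitters' processing notes; the method of background correction and normalization is stated in no label or header used here. The table holds no detection calls. The design text names the Human Gene 2.0 ST array, whereas the 21214 probe sets of the platform table, which is of the Human Gene 1.0 ST array, were all found in the deposited table by identifier, so the names of that table were used. The array medians over all probe sets lay between 6.22 and 6.34 on the log2 scale. For arrays, the number of arrays limits the precision; 2 arrays per group leave little information on the spread within a group.

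Of the probe sets, 19460 carried exactly 1 gene symbol, 1754 carried several symbols, and 12083 were not in the platform table. Of the 19460, 19429 matched the RefSeq gene table (GRCh38.p14) by Entrez identifier and 31 did not; that table was used only for current symbols, chromosomes and the order of genes along them. The 19460 probe sets stood for 18417 genes, and for the 769 genes with several probe sets the one with the highest mean over all arrays was kept. Genes above 6.27, the median of all values of the table, in at least 2 arrays were tested, which left 12639 genes. Probe sets of multi-copy families were not checked for probes shared between near-identical copies, so a value of such a gene may contain signal of its copies.

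Differences were tested on the log2 scale in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, 2-sided), and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. Across lines, the 2 arrays of each line and condition were averaged first, and the 8 line means were fitted with the line as a block, so that the line was the unit. Within lines, the 16 arrays were fitted as 8 groups sharing 1 estimate of the spread, and each HR group was set against its own parental group. An F test over 3 contrasts between the 4 HR effects asked whether the effect differed between lines. Genes called the same way in all 4 lines were those past the threshold with the same sign in each within-line test, and the count expected for independent lists was computed from the share called in each line. No label says whether the 2 arrays of a group came from separate cultures. The p-values of the within-line tests, of the F test and of list differences between lines therefore measure only the spread between these arrays. That spread may be technical. All errors are standard errors from these fits.

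Before the data were examined, 30 gene lists were fixed. They covered metabolism, stress responses, the cell cycle, antigen presentation, survival genes, plasma cell and B cell identity, adhesion, drug efflux and markers of myeloid, T and NK, and stromal cells. A gene could be in more than 1 list. Lists with at least 3 measured members were tested, 28 in all; of the mitochondrially encoded genes 0 were measured, and of the myeloid cell list 2. Each list was compared with the other genes by camera in limma with a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. The test fry, which asks only whether a list's genes moved 1 way on balance, was run beside it. Adjustment was over the 28 lists of each comparison. In 18 of the 140 list tests the median, the mean and the test differed in sign, and 0 of these 18 passed the threshold. The effect on a list in 1 line was also set against the mean of the other 3 lines by camera, in 112 tests.

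The genes named in the text follow a rule fixed at the same time. Across lines, where no gene passed, the 5 genes with the smallest p-value in each direction are named as not passing. Within lines, the 6 largest rises and 6 largest falls are named among genes past the threshold whose HR and parental arrays did not overlap, a separation that chance gives for 33.3% of genes with 2 arrays against 2. For the F test the 8 smallest p-values are named, and for genes called the same way in all 4 lines the 10 with the largest smallest absolute change. From each list up to 4 members with the smallest p-value across lines are named, together with any members needed to show which way the list went in a line. Of the 24 rises and 24 falls named within lines, 9 and 18 had a mean under the filter level of 6.27 in the lower group. Without detection calls these levels are not shown to lie above background, which compresses changes, so no fold is given for them and their log2 values and order of size may be understated. Immunoglobulin and T cell receptor segments and genes without a symbol of a known gene were counted but not named.

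Both fits were tested on simulated data of 12639 genes in which 67, 67 and 66 genes were changed by 0.5, 1 and 2 on the log2 scale. Within RPMI8226, 71.6%, 98.5% and 100% of these were recovered, and 4.26% of calls were unchanged genes. Across the 4 lines the recovered shares were 22.4%, 91.0% and 97.0% for the same sizes, and 4.76% of calls were unchanged genes. In that simulation the change was the same in every line.

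The alternatives fixed at the start were no filter, a stricter filter (above 8.12, the 75th percentile of all values, in at least 2 arrays), quantile normalization again, centring each array on its median, the mean of a gene's probe sets, a trended and robust variance prior, a minimum log2 fold of 1, an adjusted p under 0.01 for the F test, the array number within a line as a block, each array left out in turn, each line left out in turn, fits of 1 line's 4 arrays alone, and 2 other choices of the independent unit across lines. Array weights, and for cancer-testis genes a filter on parental arrays alone, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The 12083 probe sets outside the platform table and the 1754 with several symbols were left out of the comparisons because they could not be given a single gene name.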

Results

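Transcript levels were measured in 4 human lines, RPMI8226, KMS-11, U266 and IM-9, each as parental cells at 20% oxygen and as hypoxia-resistant (HR) cells at 1% oxygen, with 2 arrays per group. Arrays of a group correlated at r between 0.992 and 0.997 across probe sets, HR and parental arrays of 1 line at 0.968 to 0.991, and arrays of different lines at 0.717 to 0.813. For 16 of 16 arrays the 3 closest arrays were of the same line, and 0 pairs of arrays held identical values. Of 18417 genes with a probe set of their own, 12639 were bright enough to test. The within-line values below rest on n = 2 arrays per group, and the across-line values on n = 4 lines.

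The series asks how the transcriptome of HR cells differs from that of their parental lines, and the first comparison asked which genes shifted across the 4 lines. ANXA1, which encodes the phospholipid-binding protein annexin A1, was 1.01 ± 0.08 higher in HR cells on the log2 scale, BNIP3, a mitophagy receptor, 1.75 ± 0.15, and KDM3A, a histone H3 lysine 9 demethylase, 1.13 ± 0.10. The kinase gene MAP3K13 was 0.91 ± 0.08 higher and the zinc finger gene ZNF292 0.73 ± 0.07 higher. These 5 genes were higher in 4 of 4 lines, but none passed the correction for multiple tests (adjusted p = 0.0822 for each). The smallest p-values among lower genes belonged to FAM209B (−0.41 ± 0.06), the transcription factor gene ETS2 (−0.54 ± 0.09), POP1 (−0.36 ± 0.07), PARP12 (−0.42 ± 0.08) and GRIP1 (−0.38 ± 0.07), with adjusted p from 0.452 to 0.758, each lower in 4 of 4 lines. In limma, 0 genes rose and 0 fell across lines, while 288 higher and 505 lower genes had an unadjusted p under 0.05. With no effect at all, a share of about 0.05 of the 12639 genes tested would lie under that limit, so most of these are expected by chance. With the array number within a line as a block, 176 genes passed, with the line by condition as a random block 88, and with only the spread between arrays of a group counted 4214. These fits use the single arrays, so arrays of the same line count as separate or partly separate units, and their counts overstate the evidence across lines. With the line as the unit and RPMI8226 left out, 1 gene passed, LGMN (1.93 ± 0.09, adjusted p = 0.0253).

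Tested within each line, several genes known to respond to low oxygen rose in all 4 lines. NDRG1, a stress gene induced by low oxygen, rose by 1.26 in RPMI8226, 1.58 in KMS-11, 2.23 in U266 and 3.13 in IM-9 (± 0.11 each, log2). BNIP3 rose by 1.67, 2.05, 2.05 and 1.23 in the same order (± 0.07) and its relative BNIP3L by 0.85, 1.63, 1.54 and 0.80 (± 0.08). AK4, a mitochondrial adenylate kinase, rose by 2.32, 1.03, 5.28 and 0.81 (± 0.11). P4HA1, a subunit of the collagen prolyl hydroxylase, rose by 1.16, 2.01, 1.65 and 0.85 (± 0.08) and KDM3A by 0.86, 1.32, 1.33 and 1.00 (± 0.08). PDK1, which restrains entry of pyruvate into mitochondrial oxidation, rose by 0.78, 1.24, 1.22 and 1.00 (± 0.07) and the glycogen branching enzyme GBE1 by 0.71, 0.72, 1.24 and 1.02 (± 0.09). The heme oxygenase HMOX1 rose by 1.57, 0.78, 0.77 and 1.81 (± 0.13) and ANXA1 by 0.80, 1.13, 1.00 and 1.10 (± 0.17), its RPMI8226 value being 0.40 without parental array 1 and 1.21 without parental array 2. In all, 44 genes rose in each of the 4 lines where independent lists would share 0.458, and 10 fell in each where 2.02 would be shared. The 4 tests share each gene's estimate of the spread, so their calls are not independent and these expected counts may understate chance. Opposite calls also exceeded their expected number in most pairs of lines, as in RPMI8226 and U266 (417 against 301). The exception was KMS-11 and IM-9 (103 against 171). Of the 44, 11 belonged to the HIF target and hypoxia response list and 6 to the glycolysis list. Among the 10 that fell were the endoplasmic reticulum chaperone genes HYOU1 (−0.31, −0.23, −0.20 and −0.19, ± 0.06) and SDF2L1 (−0.27, −0.45, −0.21 and −0.27, ± 0.06). Without KMS-11 parental array 1, KMS-11 parental array 2 or KMS-11-HR array 2, 32, 33 and 34 genes rose in each line, all among the 44, and 1 fell each time. The fall found without KMS-11 parental array 2 was not among the 10, so HYOU1 and SDF2L1 were not kept there. With no filter 37 rose and 2 fell and with the stricter filter 50 and 22, so the number of shared falls depended on the setting. Of the 54, 2, NDRG1 and BNIP3, changed by at least 2-fold in each line.

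**Figure D1:**
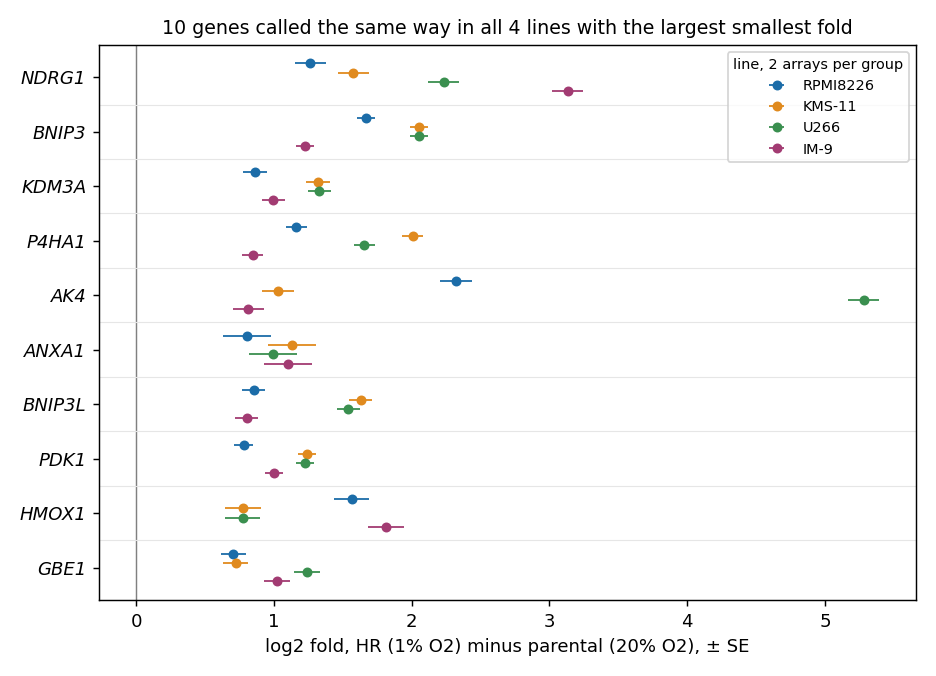
Change between HR and parental cells (log2, horizontal axis) of the 10 named genes called the same way in all 4 lines; each point is 1 line (difference of 2 HR and 2 parental arrays) and bars are standard errors. All 40 points lie above 0, from 0.71 for GBE1 in RPMI8226 to 5.28 for AK4 in U266.

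The lists of genes of the response to low oxygen were the most raised across lines. The 28 measured HIF targets had a median of 0.78 (adjusted p = 1.18e-35), and all 28 were higher on average. Over all genes 0 passed singly, and 20 rose adjusted over the list alone. The glycolysis list had a median of 0.41 over 19 genes (adjusted p = 1.89e-14), with 0 genes past the threshold and 6 risen adjusted over the list alone. Both lists had adjusted p = 0.361 with an estimated correlation. The adhesion and homing list rose with a median of 0.17 (adjusted p = 0.0406, and adjusted p = 0.444 with an estimated correlation), and its 1 gene risen adjusted over the list alone was the chemokine receptor CCR1, which rose by 0.42, 0.92, 0.54 and 0.58 (± 0.11) in RPMI8226, KMS-11, U266 and IM-9.

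Lists of mitochondrial oxidation, lipid synthesis, ribosome biogenesis and interferon genes fell across lines in the test with the preset correlation. Nuclear genes of oxidative phosphorylation had a median of −0.10 (adjusted p = 0.00053, 0 of 25 genes higher), and those of the tricarboxylic acid cycle of −0.10 (adjusted p = 0.0103); both had adjusted p = 0.361 with an estimated correlation. The MYC target and ribosome biogenesis list had a median of −0.13 (adjusted p = 0.00053, and adjusted p = 0.709 with an estimated correlation) and the interferon response list of −0.33 (adjusted p = 0.000517, and adjusted p = 0.697 with an estimated correlation). Cholesterol synthesis (median −0.39, adjusted p = 0.0232) and fatty acid synthesis (median −0.24, adjusted p = 0.0267) both had adjusted p = 0.861 with an estimated correlation, and both went the other way in RPMI8226. Of these 6 lists, adjusted over the list alone, 1 gene fell, the ribosome biogenesis factor RRS1, which was −0.29, −0.33 and −0.29 in RPMI8226, KMS-11 and U266, where it did not pass, and fell by 0.39 ± 0.11 in IM-9. The preset test called 3 lists up and 6 down of 28, the test with an estimated correlation 0, and fry 0.

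The other 19 lists did not pass across lines. Their medians were −0.01 for the unfolded protein response, −0.13 for the ATF4 and amino acid response, −0.11 for mitosis, −0.07 for DNA replication and −0.01 for p53 targets. They were 0.02 for the BCL2 family, 0.01 for plasma cell genes, 0.01 for B cell genes, −0.15 for MHC class II, −0.03 for MHC class I presentation and −0.04 for NF-kB targets. The proteasome list had a median of −0.07, heat shock −0.07, NRF2 targets −0.00, autophagy and lysosome 0.03, drug efflux and stem cell 0.06, and myeloma translocation and cyclin D −0.04. Markers of T and NK cells had a median of 0.10 and markers of stromal cells of 0.07. Adjusted over the list alone, HMOX1 of the NRF2 list rose across lines, and no other gene of these 19 lists passed.

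**Figure D2:**
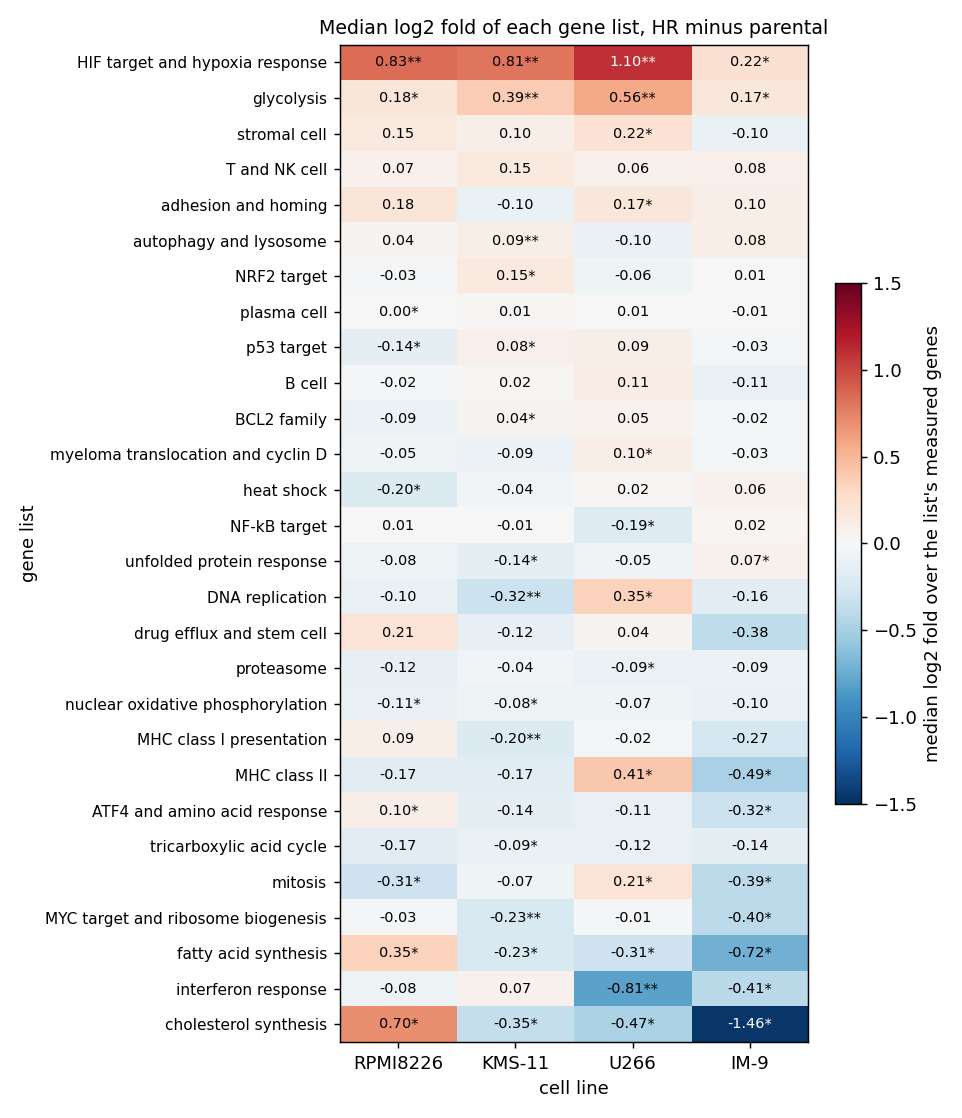
Median change between HR and parental cells (log2, colour and printed value) of each of the 28 tested gene lists (rows) in each line (columns); 1 star marks adjusted p under 0.05 with the preset correlation and a pair of stars the same with an estimated correlation. The HIF target list is positive in all 4 lines (0.83, 0.81, 1.10 and 0.22), and cholesterol synthesis runs from 0.70 in RPMI8226 to −1.46 in IM-9.

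In RPMI8226 a cancer-testis gene was among the largest rises and a tetraspanin gene among the largest falls. PAGE1, the cancer-testis gene, rose by 4.87 ± 0.09 from a parental mean of 5.15, under the filter level of 6.27 (log2, adjusted p = 3.08e-12), GATM, an enzyme of creatine synthesis, by 3.79 ± 0.09, and EGLN3, a prolyl hydroxylase that targets HIF, by 3.61 ± 0.10 (12.2-fold). CAPN6 of the calpain family rose by 3.44 ± 0.08, the insulin-like growth factor binding protein IGFBP2 by 3.31 ± 0.16 (9.93-fold) and IL2RG, the common cytokine receptor gamma chain, by 3.27 ± 0.07. TSPAN7, the tetraspanin, fell by 4.28 ± 0.11 on the log2 scale, the complement receptor CR2 fell by 3.58 ± 0.09, MME, the neutral endopeptidase CD10, fell by 2.82 ± 0.13, and CYP24A1, which inactivates vitamin D, fell by 2.79 ± 0.11. KDELR3, a receptor that returns proteins to the endoplasmic reticulum, fell by 2.51 ± 0.08 and ERRFI1, a feedback inhibitor of EGFR, fell by 2.50 ± 0.06. In total 1354 genes rose and 1934 fell (1654 and 1792 with quantile normalization again), 26.0% of those tested, and 114 and 137 of them changed by at least 2-fold. On chromosome 13, 126 of 215 genes fell and 5 rose, on chromosome 20, where CYP24A1 lies, 154 of 356 fell and 7 rose, and on chromosome 8, 156 of 447 fell and 21 rose. Chromosome 3 had the most falls, 173 of 676 genes, beside 168 rises.

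Of the HIF targets, 22 of 28 rose and 0 fell in RPMI8226 (23 adjusted over the list alone), with a median of 0.83 (adjusted p = 6.44e-22, and 0.00672 with an estimated correlation). The phosphofructokinase-2 gene PFKFB4 rose by 2.32 ± 0.09. All 16 measured cholesterol synthesis genes rose (16 adjusted over the list alone, median 0.70), led by HMGCS1, the HMG-CoA synthase, at 2.07 ± 0.08. The list had adjusted p = 3.73e-16, and adjusted p = 0.158 with an estimated correlation. Fatty acid synthesis genes rose in 8 of 14 cases (8 adjusted over the list alone, median 0.35), and glycolysis genes rose in 9 of 19 and fell in 1, the muscle phosphofructokinase PFKM (11 and 1 adjusted over the list alone, median 0.18). These calls were lost, with adjusted p = 0.271 and 0.1 with an estimated correlation. In the ATF4 and amino acid response list 9 genes rose and 2, SLC7A1 and ALDH18A1, fell (9 and 2 adjusted over the list alone, median 0.10, adjusted p = 0.283 with an estimated correlation), and PHGDH, the first enzyme of serine synthesis, rose by 1.43 ± 0.10. In the plasma cell list, called upward with a median of 0.00, 5 genes rose and 1 fell (5 and 1 adjusted over the list alone, adjusted p = 0.201 with an estimated correlation). CD38, a surface enzyme of plasma cells, rose by 1.52 ± 0.12, with ELL2, SLAMF7, LAX1 and IRF4 also up and TNFRSF17, the receptor BCMA, down. Mitosis genes fell in 12 of 21 cases and AURKB rose (12 and 1 adjusted over the list alone, median −0.31, adjusted p = 0.442 with an estimated correlation), the kinase gene AURKA being at −0.77 ± 0.09. Of the p53 targets 6 of 14 fell (6 adjusted over the list alone, median −0.14), of the heat shock genes HSPA4L, HSPH1, BAG3 and DNAJB1, 4 of 11 (4 adjusted over the list alone, median −0.20), and of the nuclear oxidative phosphorylation genes 6 of 25 (6 adjusted over the list alone, median −0.11). Adjusted p for these 3 lists was 0.271, 0.341 and 0.283 with an estimated correlation.

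KMS-11 changed least in number of genes, and 4 of its 6 largest rises, BNIP3, P4HA1, DDIT4 and BNIP3L, were members of the HIF target list. BNIP3 rose by 2.05 ± 0.07 (4.15-fold), the lysosomal protease gene LGMN by 2.03 ± 0.07 (4.08-fold), P4HA1 by 2.01 ± 0.08 (4.02-fold) and DDIT4, an inhibitor of mTOR signalling, by 1.96 ± 0.10 (3.89-fold). BNIP3L rose by 1.63 ± 0.08 (3.10-fold) and TXNIP, a thioredoxin-binding protein, by 1.59 ± 0.07 (3.01-fold). MYOF, a membrane repair protein, fell by 1.64 ± 0.08, the cationic amino acid transporter SLC7A2 fell by 1.27 ± 0.16, DSEL fell by 1.18 ± 0.08, SHISA3 fell by 1.12 ± 0.20, PLXDC2 fell by 1.01 ± 0.16 and JPH1 fell by 1.01 ± 0.12, all on the log2 scale. In total 308 genes rose and 737 fell (362 and 516 with quantile normalization again), 8.27% of those tested, and 20 and 6 of them changed by at least 2-fold. The total of 1045 was 395 and 380 without parental array 1 or 2, 401 and 348 without HR array 1 or 2, and 2083 with array weights; SHISA3 lost its call without HR array 1.

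In KMS-11, 23 of 28 HIF targets rose (26 adjusted over the list alone), with a median of 0.81 (adjusted p = 1.7e-45, and 0.000486 with an estimated correlation). Of 19 glycolysis genes 13 rose (16 adjusted over the list alone, median 0.39, adjusted p = 0.00155 with an estimated correlation). Of the DNA replication genes 16 of 21 fell and 0 rose (19 adjusted over the list alone, median −0.32, adjusted p = 0.0252 with an estimated correlation). The replication helicase factor GINS2 fell by 0.68 ± 0.09 and the helicase subunit MCM4 fell by 0.44 ± 0.07. In the MYC target and ribosome biogenesis list 7 of 18 genes fell (14 adjusted over the list alone, median −0.23, adjusted p = 0.0235 with an estimated correlation). In the MHC class I presentation list 2 of 10 fell (5 adjusted over the list alone, median −0.20, adjusted p = 0.0356 with an estimated correlation), the peptide transporter TAP1 and the immunoproteasome subunit PSMB9. Autophagy and lysosome genes rose in 3 of 15 cases (5 adjusted over the list alone, median 0.09, adjusted p = 0.0407 with an estimated correlation), the autophagosome gene GABARAPL1 by 0.64 ± 0.10 beside WIPI1 and the protease CTSD. Cholesterol synthesis genes fell in 10 of 16 cases (13 adjusted over the list alone, median −0.35) and the fatty acid synthesis genes FASN, ACACA, ACSL1, FADS1 and ELOVL5 fell, 5 of 14 (9 adjusted over the list alone, median −0.23). The 2 lipid lists had adjusted p = 0.129 and 0.159 with an estimated correlation. Unfolded protein response genes fell in 6 of 21 cases (8 adjusted over the list alone, median −0.14, adjusted p = 0.155 with an estimated correlation), and the chaperone HSPA5 fell by 0.42 ± 0.07. Of the NRF2 targets HMOX1, SRXN1 and TXNRD1 rose, 3 of 13 (4 adjusted over the list alone, median 0.15, adjusted p = 0.0977 with an estimated correlation). The BCL2 family was called upward with 2 genes up, the pro-apoptotic BMF and BCL2L11, and 1 down, PMAIP1, also pro-apoptotic (2 and 1 adjusted over the list alone, median 0.04). The p53 targets were called upward with 1 gene, TP53INP1 (1 adjusted over the list alone, median 0.08). Adjusted p for the BCL2 family and p53 lists was 0.115 and 0.215 with an estimated correlation. Of the oxidative phosphorylation genes CYC1 and NDUFS3 fell and of the tricarboxylic acid cycle genes CS and PDHA1, 2 each (4 and 3 adjusted over the list alone, medians −0.08 and −0.09). Their adjusted p was 0.233 and 0.215 with an estimated correlation.

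In U266 the HIF target and glycolysis lists rose and the interferon response list fell. AK4 rose by 5.28 ± 0.11 from a parental mean of 4.95, under the filter level (log2), HK2, a hexokinase, by 3.06 ± 0.12 (8.32-fold) and IDO1, which degrades tryptophan, by 3.19 ± 0.11. The adaptor gene SLA rose by 2.93 ± 0.13 (7.64-fold), the teneurin gene TENM3 by 2.92 ± 0.07 (7.59-fold) and the zinc finger gene ZNF730 by 2.87 ± 0.21 (7.33-fold). The interferon-induced genes IFIT1, IFIT3 and MX1 fell by 1.99 ± 0.17, 1.81 ± 0.15 and 1.77 ± 0.07 on the log2 scale, PSTPIP2 fell by 2.79 ± 0.10, the actin-bundling gene PLS3 fell by 1.82 ± 0.10 and ALLC fell by 1.75 ± 0.13. In total 1223 genes rose and 1064 fell, 18.1% of those tested, and 173 and 57 of them changed by at least 2-fold. The total of 2287 was 1461 without parental array 1, 1425 without HR array 1 and 1476 without HR array 2.

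Of the interferon response genes 13 of 18 fell and 1, MX2, rose in U266 (15 and 1 adjusted over the list alone), with a median of −0.81 (adjusted p = 1.16e-11, and 0.00248 with an estimated correlation). HIF targets rose in 27 of 28 cases (27 adjusted over the list alone, median 1.10, adjusted p = 0.00099 with an estimated correlation). Glycolysis genes rose in 14 of 19 cases and PFKM fell (16 and 1 adjusted over the list alone, median 0.56, adjusted p = 0.00248 with an estimated correlation). DNA replication genes rose in 15 of 21 cases (16 up and 1 down adjusted over the list alone, median 0.35, adjusted p = 0.0737 with an estimated correlation), MCM7 among them by 0.56 ± 0.07. Mitosis genes rose in 7 of 21 cases (10 adjusted over the list alone, median 0.21, adjusted p = 0.36 with an estimated correlation), AURKA among them by 0.39 ± 0.09. MHC class II genes rose in 4 of 8 cases (5 adjusted over the list alone, median 0.41, adjusted p = 0.216 with an estimated correlation), HLA-DPA1 by 0.57 ± 0.12 beside HLA-DPB1, HLA-DMA and HLA-DMB. The myeloma translocation and cyclin D list was called upward with 2 of 6 genes, the transcription factor MAF by 2.17 ± 0.11 and the cyclin CCND2 by 0.66 ± 0.07. Its count adjusted over the list alone was also 2, its median 0.10 and its adjusted p = 0.159 with an estimated correlation. In the adhesion and homing list 5 genes rose and 2 fell (5 and 2 adjusted over the list alone, median 0.17, adjusted p = 0.219 with an estimated correlation). The integrin ITGB7 rose by 1.38 ± 0.11, beside ITGA6, CD44, CCR1 and CXCR4, and NCAM1, the neural cell adhesion molecule, fell by 1.17 ± 0.11, beside the integrin ITGA4. Cholesterol synthesis genes fell in 13 of 16 cases (16 adjusted over the list alone, median −0.47) and fatty acid synthesis genes fell in 8 of 14 while THRSP rose (9 and 1 adjusted over the list alone, median −0.31). Both lipid lists lost their call, with adjusted p = 0.159 and 0.266 with an estimated correlation. The NF-kB targets NFKBIA, NFKB2, TNFAIP3 and CCL3 fell, 4 of 13 (5 adjusted over the list alone, median −0.19). The proteasome genes PSMB5, PSMB6, PSMB7 and PSMD11 fell, 4 of 23, and PSMA7 rose (6 and 1 adjusted over the list alone, median −0.09). These 2 lists also lost their call, with adjusted p = 0.0737 and 0.36 with an estimated correlation. The stromal cell list was called upward with 2 of 6 genes, the cell surface protein THY1 by 2.37 ± 0.09 and the fibronectin FN1 by 0.28 ± 0.08 (2 adjusted over the list alone, median 0.22, adjusted p = 0.277 with an estimated correlation). The collagen genes COL1A1, COL3A1, COL6A1 and COL6A2 were at 0.17, −0.00, 0.26 and 0.02 and did not pass.

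IM-9 had the most genes past the threshold in the fit that pools the spread over the 8 groups. X-linked cancer-testis genes were among its rises and lipid synthesis genes among its falls. MAGEC2 rose by 4.21 ± 0.18, PAGE2B by 4.19 ± 0.18 (18.3-fold), SSX3 by 4.14 ± 0.17 (17.6-fold) and FMR1NB by 3.43 ± 0.15; PAGE2B and SSX3 belong to families of near-identical copies. ROBO2, a guidance receptor, rose by 3.81 ± 0.10 and the growth factor BMP4 by 3.71 ± 0.10. The organic anion transporter SLCO4C1 fell by 4.95 ± 0.21 on the log2 scale, the noncoding RNA AFAP1-AS1 fell by 3.54 ± 0.08 and ITM2A fell by 3.44 ± 0.12. HMGCS1 fell by 2.36 ± 0.08, ME1, the malic enzyme that supplies NADPH, fell by 2.30 ± 0.08, and DHCR7, the last enzyme of cholesterol synthesis, fell by 2.20 ± 0.08. In total 1814 genes rose and 2692 fell, 35.7% of those tested. Of these, 174 and 79 changed by at least 2-fold, against 114 and 137 in RPMI8226, so the lead of IM-9 was small at that size. The total of 4506 was 2843 in a fit of the 4 IM-9 arrays alone, and centring each array on its median gave 2122 rising and 1889 falling genes.

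In IM-9 all 16 measured cholesterol synthesis genes fell (16 adjusted over the list alone), with a median of −1.46 (adjusted p = 2.24e-16, and adjusted p = 0.103 with an estimated correlation). Of 14 fatty acid synthesis genes 12 fell (12 adjusted over the list alone, median −0.72, adjusted p = 0.103 with an estimated correlation), and the desaturase SCD fell by 1.80 ± 0.11. HIF targets rose in 14 of 28 cases and fell in 2, ANKRD37 (−0.65 ± 0.07) and DDIT4 (−0.54 ± 0.10). Adjusted over the list alone 15 rose and 3 fell, the median was 0.22 and adjusted p = 0.103 with an estimated correlation. Glycolysis genes rose in 9 of 19 cases and PFKM fell (10 and 1 adjusted over the list alone, median 0.17, adjusted p = 0.103 with an estimated correlation). Unfolded protein response genes rose in 10 of 21 cases, and SDF2L1, HYOU1 and PDIA6, 3 of 21, fell (10 and 4 adjusted over the list alone, median 0.07, adjusted p = 0.315 with an estimated correlation), and SEL1L, an adaptor of protein degradation, rose by 0.96 ± 0.10. In the ATF4 and amino acid response list 14 of 22 genes fell and 1, DDIT3, rose (17 and 1 adjusted over the list alone, median −0.32, adjusted p = 0.224 with an estimated correlation). PHGDH was at −1.27 ± 0.10 and the asparagine synthetase ASNS at −1.05 ± 0.07. Mitosis genes fell in 13 of 21 cases (13 adjusted over the list alone, median −0.39, adjusted p = 0.38 with an estimated correlation), the cyclin CCNB1 at −0.90 ± 0.10. In the MYC target and ribosome biogenesis list 13 of 18 genes fell (14 adjusted over the list alone, median −0.40, adjusted p = 0.103 with an estimated correlation), MYC itself at −0.77 ± 0.06. MHC class II genes fell in 6 of 8 cases (8 adjusted over the list alone, median −0.49, adjusted p = 0.203 with an estimated correlation). Interferon response genes fell in 9 of 18 cases, and 2 members that moved apart were IFIT3 at −1.95 ± 0.15 and MX2 at 0.72 ± 0.09, the 1 that rose. The list had 10 genes down and 1 up adjusted over the list alone, a median of −0.41 and adjusted p = 0.179 with an estimated correlation. Of the 2 measured myeloid markers, CD68, a lysosomal protein, rose by 1.11 ± 0.10 and the neutrophil elastase gene ELANE, at −0.12 ± 0.11, did not pass.

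The last comparison asked whether the HR effect differed between lines. HMGCS1 rose by 2.07 in RPMI8226 and fell by 0.61 in KMS-11, fell by 1.00 in U266 and fell by 2.36 in IM-9 (± 0.08, log2). LAPTM5, a lysosomal membrane protein of blood cells, was −1.05 in RPMI8226 and 2.54 in U266 (± 0.06, both past the threshold). PAGE1, GATM, IL2RG and CD48, a surface glycoprotein of lymphocytes, rose by 4.87 ± 0.09, 3.79 ± 0.09, 3.27 ± 0.07 and 3.20 ± 0.07 in RPMI8226 against values between −0.47 and 0.41 in the other lines. In IM-9 CNBD1 rose by 3.01 ± 0.07, against values between −0.04 and 0.01 in the other lines, and AFAP1-AS1 was −3.54 ± 0.08, against 0.32, −0.79 and 0.86 in RPMI8226, KMS-11 and U266. Adjusted p in the F test was between 2.67e-10 and 3.72e-10 for these 8 genes. The effect differed for 5741 of 12639 genes (45.4%), and 1361 of these were called in opposite directions in at least 2 lines. The F test measures these differences against the spread between duplicate arrays only. A difference between lines therefore cannot be told from one between the particular cultures sampled. Of 7329 genes called in at least 1 line, 4429 were called in exactly 1. At an adjusted p under 0.01 the count was 3664.

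**Figure D3:**
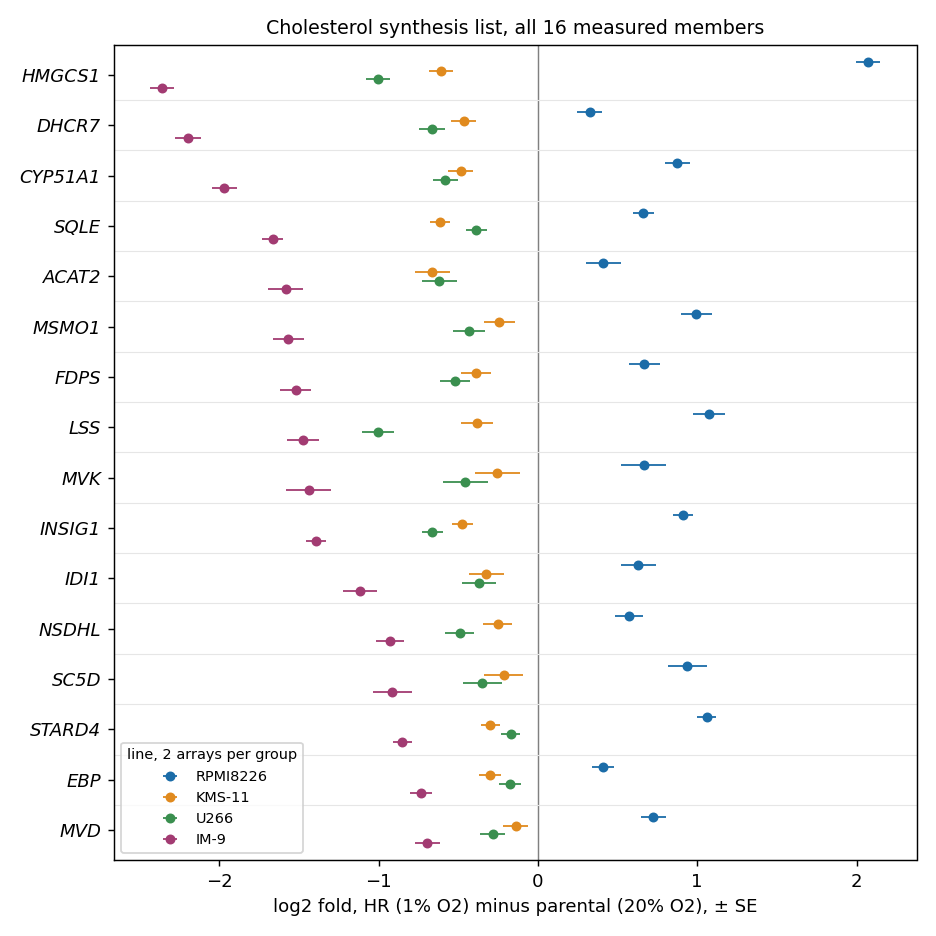
Change between HR and parental cells (log2, horizontal axis) of the 16 measured members of the cholesterol synthesis list; each point is 1 line (difference of 2 HR and 2 parental arrays) and bars are standard errors. All RPMI8226 points lie above 0 and all IM-9 points below 0, with HMGCS1 at 2.07 and −2.36 as the widest apart.

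Gene groups also differed between lines when each line was set against the mean of the other 3. Cholesterol synthesis was at 1.46 in RPMI8226 and −1.34 in IM-9 (median difference, log2), and fatty acid synthesis at 0.75 and −0.68. DNA replication was at −0.37 in KMS-11 and 0.52 in U266. HIF targets were at 0.42 in U266 and −0.54 in IM-9, mitosis genes at 0.42 and −0.35, and MHC class II genes at 0.60 and −0.43. Of 112 such differences 37 passed with the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.0503). Across all genes the changes of line pairs correlated weakly, from r = 0.033 for RPMI8226 and U266 to 0.236 for KMS-11 and IM-9; genes are not independent replicates. Of the 12639 genes, 16.4% had the same sign in all 4 lines, against 12.5% by chance.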

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

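The tests of scaling and of a shared oxygen effect on cholesterol synthesis were chosen after the result was seen; the test of further sterol targets and the regroupings of the line means were planned before theirs.

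Cholesterol synthesis genes moved in opposite ways, with all 16 members rising in RPMI8226-HR (median 0.70) and all 16 falling in IM-9-HR (median −1.46). The tables argue against scaling between arrays, since under quantile normalization again and under median centring the smaller of the 2 absolute medians was still 0.703. They also argue against an effect of low oxygen shared by the 4 lines as the whole cause, since 16 members rose in RPMI8226 while 10, 13 and 16 fell in KMS-11, U266 and IM-9. A candidate explanation is a shift of the sterol response beyond the synthesis enzymes: 8 further targets had a median of −0.68 in IM-9, with 6 falling and NPC1 at 0.03, and of 0.35 in RPMI8226, with 5 rising, SREBF2 at 0.0964 and CYB5B at −0.0774, against −0.10 in KMS-11 and −0.22 in U266, where ACSS2 rose by 0.67, so this explanation stays open as a hypothesis. Whether the resistant state, the oxygen level or the culture medium of each line set the direction was not tested, since the design confounds the first with the second and the labels used here do not compare media.

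The HR effect differed between lines in the F test for each of these genes, with a range between the highest and lowest line of 4.798 for PAGE1, 3.59 for LAPTM5, 4.43 for HMGCS1, 3.52 for CD48, 4.40 for AFAP1-AS1, 3.05 for CNBD1, 4.26 for GATM and 3.14 for IL2RG, all on the log2 scale.

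For each gene list with a difference between a line and the mean of the other 3 past the threshold with the preset correlation, the one with the smallest p-value is given as a median difference (log2). In RPMI8226 it was 1.46 for cholesterol synthesis, 0.75 for fatty acid synthesis, 0.31 for the ATF4 and amino acid response, −0.27 for p53 targets, −0.14 for heat shock and −0.0921 for the BCL2 family. In KMS-11 it was −0.37 for DNA replication, 0.45 for the interferon response, 0.16 for NRF2 targets, −0.18 for MHC class I presentation, 0.18 for autophagy and lysosome and −0.38 for adhesion and homing. In U266 it was 0.42 for mitosis, 0.22 for glycolysis, 0.60 for MHC class II, −0.0712 for NF-kB targets, 0.21 for B cell genes and 0.21 for myeloma translocation and cyclin D. In IM-9 it was −0.54 for HIF targets, 0.17 for the unfolded protein response and −0.30 for MYC targets and ribosome biogenesis. For 5 of these lists another line had a larger median difference past the threshold: 0.52 for DNA replication and −0.67 for the interferon response in U266, −0.37 for the ATF4 and amino acid response and −0.28 for glycolysis in IM-9, and 0.22 for NF-kB targets in RPMI8226. With an estimated correlation 0 of the 112 differences passed.

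The median of 1 line lay far from the other 3 in 2 of 45 groups of 4 lines tested: NF-kB targets in U266, at −0.19, and T and NK cell markers in KMS-11, at 0.15. Chance flags about 1 in 20 groups.

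Among 6557 bright probe sets without a single gene symbol, which the comparisons did not use, 3 were called upward in all 4 lines and 0 downward, where independent lists would share 0.00246 and 0.00155.

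The 8 line means were regrouped in 32 ways, the real one included. For gene lists called across lines with the preset correlation, 9 of 32 gave at least as many as the real count of 9, and the highest other gave 12. The regroupings ignored the line pairs, and many put both means of a line on the same side, where the line block removes that line. Some of these still set HR against parental cells in the lines that remained, so they carry the real effect. The 32 counts are therefore not a chance distribution, and swaps within lines alone are too few to give one. Whether chance gave the list count could not be decided, and chance is not excluded. For genes the real count was 0 and the highest other 1; a count of 0 is reached by all 32 in any case, so the regroupings say nothing on genes. A further 3 regroupings left nothing to estimate beside the line block.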

How the results depend on the processing

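Array weights and a filter on parental arrays alone for cancer-testis genes were chosen after seeing the data; the other alternatives were fixed before the data were examined. Except where a value below shows otherwise, each total of called genes, and of lists called across lines, stayed within 1.5 times its reported value. The across-line count of 0 genes was 176 with the array number within a line as a block (replicate block), 4214 with the mean of the 4 contrasts over 16 arrays, 88 with the line by condition as a random block, and between 0 and 1 with an array or a line left out; the unit of replication assumed by each fit differs by construction. Deviations of arrays with the same number correlated across genes at 0.205, 0.0712, −0.048 and 0.109 in RPMI8226, KMS-11, U266 and IM-9, so the numbers were not treated as pairs, and the within-line totals with that block were 3303, 939, 2315 and 4610. Of the 9 lists called across lines, 0 passed camera with an estimated correlation and 0 passed fry. Within lines camera with the preset correlation called 6 lists up and 4 down in RPMI8226, 6 and 8 in KMS-11, 8 and 5 in U266 and 3 and 7 in IM-9, whereas 1, 6, 3 and 0 lists passed with an estimated correlation and 24, 16, 20 and 24 passed fry. Of the 37 list differences between lines 0 passed with an estimated correlation. With an absolute log2 fold of at least 1 the totals were 251 in RPMI8226, 26 in KMS-11, 230 in U266, 253 in IM-9 and 2 called the same way in all 4 lines, which a size minimum lowers by construction, and an adjusted p under 0.01 left 3664 genes in the F test.

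Leaving out 1 array at a time gave 348 to 1208 genes in KMS-11, 1425 to 2530 in U266 and 33 to 56 called the same way in all 4 lines, 32 to 45 of them rising and 1 to 12 falling, and each group that lost an array was assumed to vary like the others; the lowest values came with arrays of KMS-11 or U266 themselves, which leaves fewer arrays in the contrast. Array weights gave 2083 genes in KMS-11, and the 4 IM-9 arrays alone gave 2843 in IM-9. The SD over genes of the difference between duplicate arrays was 0.203 in IM-9 parental and 0.131 in IM-9-HR cells. In KMS-11 parental and HR cells it was 0.131 and 0.128. A spread pooled over the 8 groups therefore tends to raise the count in IM-9 and to lower it in KMS-11. How much of either change this explains was not tested. Genes called the same way, 44 rising and 10 falling as reported, were 37 and 2 with no filter, 50 and 22 with the stricter filter, 50 and 3 with quantile normalization again, 44 and 6 with median centring, 48 and 19 with a trended and robust prior and 43 and 16 with array weights. The share rising among called genes also moved: IM-9 had 2122 up and 1889 down with median centring and 2150 and 2323 with quantile normalization again, against 1814 and 2692. With quantile normalization again RPMI8226 had 1654 up and 1792 down, against 1354 and 1934, and KMS-11 362 and 516, against 308 and 737. U266 then had 1219 and 1171, against 1223 and 1064. The excess of falls in RPMI8226 and KMS-11 thus depended in size on the scaling. In IM-9 it became an excess of rises with median centring. Median centring gave 1303 and 1695 in RPMI8226, 261 and 608 in KMS-11 and 1089 and 1036 in U266.

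Of single named genes, 2 changed sign, neither past the threshold in the reported fit. ELANE in IM-9 was 0.11 without IM-9 parental array 1 and −0.36 without parental array 2, and GNLY in IM-9 was −0.0666 and 0.38 in the same order; the cause was not tested. For named genes within lines, 80 results lost and 11 gained their call when an array was left out while 2531 kept their side of the threshold, and under the other settings 32 lost and 11 gained it while 1392 kept their side. For genes across lines, 45 results gained a call under other settings, 106 were alike, and 340 of 340 were alike with an array or line left out. The gains were 15 with the replicate block, 13 with the random block and 17 with the mean of the 4 contrasts. None of these fits has the line as its unit. For lists, 55 results lost their call with an array or line left out and 877 kept their side of the threshold, and under the other settings 78 lost it and 369 kept their side. The deposited table holds no background level or detection call, so signal over background could not be given, and genes near the filter are the least certain.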

Other observations

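The genes and regions singled out in this part were chosen after their values were seen, and so were the tests on chromosome 13, on cancer-testis genes with no filter, on RNA of another line, on the X chromosome and on gene families; the test of germline genes on other chromosomes was planned before its result.

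In U266-HR, MAF, a transcription factor that is driven by translocation in some myelomas, rose from 6.26 to 8.44 (log2 means of 2 arrays), and ITGB7 and CCND2, 2 known targets of MAF, rose from 8.96 to 10.33 and from 10.88 to 11.54. In RPMI8226 and KMS-11, MAF was already at 10.29 and 10.14 in parental cells, and its changes of −0.09 ± 0.11 and 0.09 ± 0.11 did not pass. Known targets also moved in lines where MAF did not pass: CCND2 fell by 0.32 on the log2 scale in IM-9 (adjusted p = 0.00234), where MAF was at 0.02, and CCR1 rose by 0.42, 0.92 and 0.58 in RPMI8226, KMS-11 and IM-9, besides 0.54 in U266. The cancer-testis genes SSX1, MAGEB16 and CSAG1 rose by 2.79, 2.00 and 1.53 in U266.

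In RPMI8226-HR, genes of chromosome 13 were lower as a block, with a median of −0.31 over 215 genes, 126 of them falling and 5 rising. Chromosome 20 had a median of −0.20 over 356 genes and chromosome 8 of −0.15 over 447. Medians of the other 20 chromosomes lay between −0.06 and 0.04, and those of every chromosome of the other lines between −0.12 and 0.09. A median can hide a mixed or partial shift. In RPMI8226, 168 of 676 genes on chromosome 3 rose and 173 fell. In IM-9, 124 of 390 genes on chromosome 14 rose, where 1814 of all 12639 did. In U266, 38 of 142 genes on chromosome 21 fell, where 1064 of all 12639 did, and on chromosome 20, 84 of 356 rose and 58 fell. For chromosome 13, a shift of the arrays' level is argued against by random lists matched on mean level. Of these, 0% of 10000 had a median as low (lowest −0.08). A few strongly lowered genes are argued against by the 85.1% of its genes below 0. Loss of copies of chromosome 13 in the HR cells may account for it, since the medians of the first, middle and last part of its genes in order were −0.28, −0.36 and −0.31, but no DNA was measured, and it remains a hypothesis.

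In IM-9-HR, 12 of 24 measured X-linked cancer-testis genes rose and 1 fell, where 3.44 would rise at the share of all genes, and since the filter can let in a gene because it rose, 12 of 41 rose with no filter, where 3.97 would, and 9 of the 19 let in by parental arrays alone, where 2.38 would. In RPMI8226, KMS-11 and U266, 2, 0 and 6 of the 24 rose where 2.57, 0.585 and 2.32 would, with no filter 2, 0 and 5 of the 41 where 2.73, 0.543 and 2.59 would, and of the 19 let in by parental arrays alone 1, 0 and 2 where 1.61, 0.331 and 1.52 would, while in U266 2 fell, DDX53 and SAGE1. Besides those named earlier, MAGEA1 rose by 2.58, MAGEC1 by 1.75, PAGE2 by 1.84, SSX1 by 1.44, SSX5 by 2.04 and SSX7 by 2.04. RNA of RPMI8226, KMS-11 or U266 is argued against, since genes far higher in those lines had medians of at most 0.0266 in IM-9-HR. Of these genes 13 of 51, 10 of 38 and 11 of 50 rose, however, against 14.4% of all genes. A rise of the whole X chromosome is argued against by a median of −0.0263 over 415 other genes. Probes shared within 1 family are argued against as the only source by rises in 5 families. Sharing within several families, PAGE and SSX among them, was not checked, so the 12 rises may count the same signal repeatedly. A general release of germline genes cannot be told apart from a release limited to the X chromosome, since 0% of the germline genes on other chromosomes rose but only 6 were measured, and a selected subclone and a response to low oxygen both stay open, as untested.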
